A study of Mus musculus with 8 samples.

How the data were processed

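Polyadenylated RNA of haematopoietic stem cells (HSCs) sorted from the bone marrow of 8 mice, 4 wild type and 4 Nupr1-/-, was reverse transcribed by a published method and made into Nextera XT libraries, 1 per mouse, per the labels' protocols. The kit does not mark the strand of a read. Per the submitters' processing notes the tools were bcl2fastq, HISAT2, featureCounts, Subread and DESeq2 and the genome build mm10, with no versions and no settings.

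The deposited table holds a normalised signal per gene for the 8 libraries, which by the values themselves are gene read counts divided by 1 size factor per library, although the table is presented as raw counts. In each library all values (100%) were whole multiples of a single step within a tolerance of 0.001, and size factors recomputed from the recovered reads by the median-of-ratios method differed from these steps, as ratios, by at most 8.83e-11. Dividing by the step gave back whole reads, 2296101 to 4769401 per library. The step of wild type library 3 is so near to 1 that for this library the recovery rests on its low values, none of which is a whole number. The table has 11855 entries, 1 of them without a name. Every entry was above 0 in at least 3 libraries and 10166 in all 8, so genes seen in fewer libraries were not analysed here. Only 6 of 79 ribosomal protein genes and 0 mitochondrially encoded genes were among them. A further 17 names look like dates, as spreadsheet programs make from some symbols, and were left as they are. Of 11853 distinct symbols 11716 were matched to GENCODE M21 (mm10), 453 of them through an older symbol, for positions, exon overlaps, GC content and transcript length.

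The test planned for raw counts, the edgeR quasi-likelihood test with TMM factors, was replaced as the main test because the table holds normalised values. Run on the recovered reads, the planned test passed 336 genes, against 418 with the limma test given next. Camera on the planned fit passed 1 gene list, against 4 in the main list test. Values were put on the log2 scale after adding 1, genes with a value of at least 10 in at least 4 libraries were kept (10989 tested, 865 left out), and groups were compared with limma 3.58.1 (eBayes with trend and robust) in R 4.3.3, two-sided, with Benjamini-Hochberg adjusted p under 0.05. Log2 changes are libraries labelled knockout minus wild type. Folds are those of the log2 scale. Means are of normalised reads, with SD over 4 mice. With 4 against 4, exact permutation tests have 70 assignments and a smallest p of 0.0286. The added value of 1 and the filter were set after trial fits with added values of 1, 5 and 10 and with edgeR and DESeq2 had been seen, and 1 gave the fewest genes of the 3. The grouping, the gene lists, the rule for named genes and the settings said below to be set in advance were set before the data were examined.

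Gene lists were tested with camera of limma (preset correlation 0.01, two-sided, adjusted over the 24 of 32 lists with at least 5 tested genes), with a variance trend to match the gene test. Camera without that trend, its default, had been run first and passed 1 list, and the trend, with which 4 lists pass, was chosen after that. The lists were p53 target genes, p53 regulators and partners, G1/S and S phase, G2/M phase, cyclin-dependent kinases with cyclins and inhibitors, HSC identity, multipotent progenitor and lineage priming, immediate early and stress response, endoplasmic reticulum stress and ATF4, autophagy and lysosome, apoptosis, iron with ferroptosis and antioxidant, oxidative phosphorylation, glycolysis, cytosolic ribosomal proteins, ribosome biogenesis and MYC targets, interferon response, DNA repair, mTOR with PI3K and FOXO, and the genes near Nupr1 on chromosome 7. Further lists held mitochondrially encoded genes, Y-linked and X-inactivation genes, and markers of erythroid cells, neutrophils, monocytes and macrophages, B cells, T and NK cells, megakaryocytes and platelets, mast cells with basophils and eosinophils, dendritic cells, endothelial cells, and bone and stromal cells.

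The genes to name were picked by a rule, and not every gene picked is named. They were Nupr1, then the 12 of smallest p in each direction among called genes with no predicted name and no overlap between the 4 values of each group. From each biology list came its called members, at most 4, or, with fewer than 2, the 2 of smallest p as values. Trp53, Mdm2, Mdm4, Cdkn1a, Ccng1, Bbc3, Bax, Mki67, Cdk6 and Cdkn1c were always named, as were called genes of the chromosome 7 list (at most 4) and the 2 members of highest mean from each list of another cell type. Genes named outside this rule are said to be chosen after their values were seen. Uty, Kdm5d, Eif2s3x, Ddx3x, Kdm6a and Kdm5c, given beside Xist, were also named outside the rule, and their naming was not set in advance.

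The other settings set in advance were DESeq2 1.42.0, limma-voom with sample weights, edgeR 4.0.16 with RLE factors, upper quartile factors or library size alone, no filter, a filter on CPM, the replicate number as a block, each library left out in turn, adjusted p under 0.1, a test against 1.5-fold, and for lists camera with an estimated correlation and fry. EdgeR with TMM factors, the test first planned, was kept as an alternative on recovered reads. Those chosen after seeing the data were added values of 5 and 10 and values rescaled by TMM factors or to equal column sums. Chosen then as well was camera with an estimated correlation in fits with 1 library left out or the GC trend removed. The last was removal from each library of natural splines (4 degrees of freedom each) in GC content and log transcript length, with and without wild type library 2. That removal covered the 10889 tested genes with a GC content (99.1%). Library measures compared were reads, genes with reads, the share of the 50 most abundant genes (18.3% ± 0.758 in libraries labelled knockout, 18.1% ± 1.36 in wild type, SD, n = 4; exact permutation p = 0.857) and the correlation with GC content. The last replaced the planned share of mitochondrial reads, which the genes analysed do not give.

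The main test was tested on simulated data made from the recovered reads with their dispersions. Of 200 changed genes it called 16% of those changed 2-fold and 63% of those changed 4-fold, with 5 false calls among 84. With no changed gene and the GC trend of the real libraries it made 4 calls, and 0 after removal of the trend. With changed genes, the trend and its removal it recovered 19% and 71%. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.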

Results

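Haematopoietic stem cells (HSCs), the bone marrow cells that renew themselves and give rise to the blood lineages, were sorted from 4 wild type and 4 Nupr1-/- mice on a C57BL/6 background, and polyadenylated RNA was sequenced with 1 library per mouse. Nupr1 is a small stress-induced nuclear protein that binds chromatin. The series title names the quiescence of HSCs and p53 signalling, and the single comparison, libraries labelled knockout against wild type, asks how the stem cell transcriptome differed between the genotypes. The reads recovered from the deposited values numbered 4769401, 3340217, 3404008 and 4500923 in wild type libraries 1 to 4. They numbered 2296101, 2680097, 3959564 and 3518618 in libraries 1 to 4 labelled knockout. Genes with reads numbered 11553, 11018, 11534 and 11485 in the wild type libraries and 11521, 11603, 11446 and 11701 in those labelled knockout. Neither measure passed its test (reads, exact permutation p = 0.171, adjusted over 4 library measures 0.343; genes, exact permutation p = 0.314, adjusted 0.419; 70 assignments, smallest possible p 0.0286, two-sided).

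Nupr1 was read in all 8 libraries. The gene (ENSMUSG00000030717.9, protein-coding) lies on mm10 chromosome 7 from 126623249 to 126630861 on the minus strand, and its exons overlap no other annotated exon. Normalised read counts were 285.5, 134.0, 245.3 and 318.2 in wild type libraries 1 to 4 and 179.4, 173.3, 200.6 and 118.5 in libraries 1 to 4 labelled knockout. The mean was 168 ± 34.96 (SD, n = 4) in libraries labelled knockout, which is 68.3% of the wild type mean of 246 ± 80.2 (SD, n = 4). The log2 difference of -0.50 ± 0.34 (SE) did not pass the test (limma adjusted p = 0.433; exact permutation p = 0.143), and the groups overlapped. A value per gene does not show which exons were read, and the deleted part of the gene is not given in the sources used here. The targeted gene therefore does not separate the groups, and each difference below is between the libraries as labelled.

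Trp53, which encodes the tumour suppressor and transcription factor p53, had the smallest p of the 10989 genes tested. It fell 5.63-fold, from 548 ± 74.99 to 99.4 ± 28.2 normalised reads (SD, n = 4), a log2 change of -2.49 ± 0.31 (SE, limma adjusted p = 0.00155). All 4 libraries labelled knockout (58.6 to 118.5) lay below all 4 wild type libraries (450.5 to 617.5). The gene lies on chromosome 11 from 69580359 to 69591873 on the plus strand and shares no exon sequence with another gene. It was also the single gene past a test against a minimum change of 1.5-fold (adjusted p = 0.0319). A value per gene does not show which exons were read, and whether the mice also carry an altered Trp53 allele is not given in the sources used here.

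Xist, the non-coding RNA that coats the inactive X chromosome of female cells, was 122.5, 107.2, 113.1 and 159.3 normalised reads in libraries 1 to 4 labelled knockout. In wild type it was 11.8 in library 2 and 0 in libraries 1, 3 and 4 (limma log2 change 6.05, SE 1.0618, adjusted p = 0.00812). Tsix, its antisense partner, added here after its values were seen, averaged 388 ± 57.4 against 63.7 ± 97.1 (SD, n = 4; adjusted p = 0.0238). Tsix missed the threshold in DESeq2 (0.0998), in edgeR (0.121 to 0.137), with the GC trend removed (0.0754, log2 change 3.83 before and 4.07 after) and in 5 of the 8 fits that left out 1 library (highest 0.0886). Wild type library 2 had 208.9 for Tsix and the other wild type libraries 4.5 to 22.3. The exons of Xist and Tsix overlap on opposite strands, and the library kit (Nextera XT) does not mark the strand, so reads in the overlap cannot be assigned to either. Of the Y-linked genes, Uty averaged 2.24 ± 3.06 in libraries labelled knockout and 21.99 ± 14.4 in wild type, and Kdm5d 16.4 ± 6.47 and 39.1 ± 20.54 (Kdm5d adjusted p = 0.461; Uty was below the filter on low values). By library Uty was 0, 2.5, 0 and 6.5 in those labelled knockout and 23.7, 3.0, 37.9 and 23.4 in wild type, and Kdm5d 14.6, 13.7, 11.5 and 25.9 against 68.2, 33.5, 19.9 and 34.8. Of X-linked genes that escape inactivation, Eif2s3x was 782 ± 134 against 994 ± 216 in wild type, Ddx3x 1258 ± 124 against 1487 ± 339, Kdm6a 82.9 ± 38.6 against 56.4 ± 27.1 and Kdm5c 107.7 ± 27.3 against 82.2 ± 31.2 (SD, n = 4; limma adjusted p = 0.380, 0.547, 0.632 and 0.634). Naming these Y-linked genes and genes that escape inactivation was not set in advance. The labels give no sex for the mice.

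**Figure D1:**
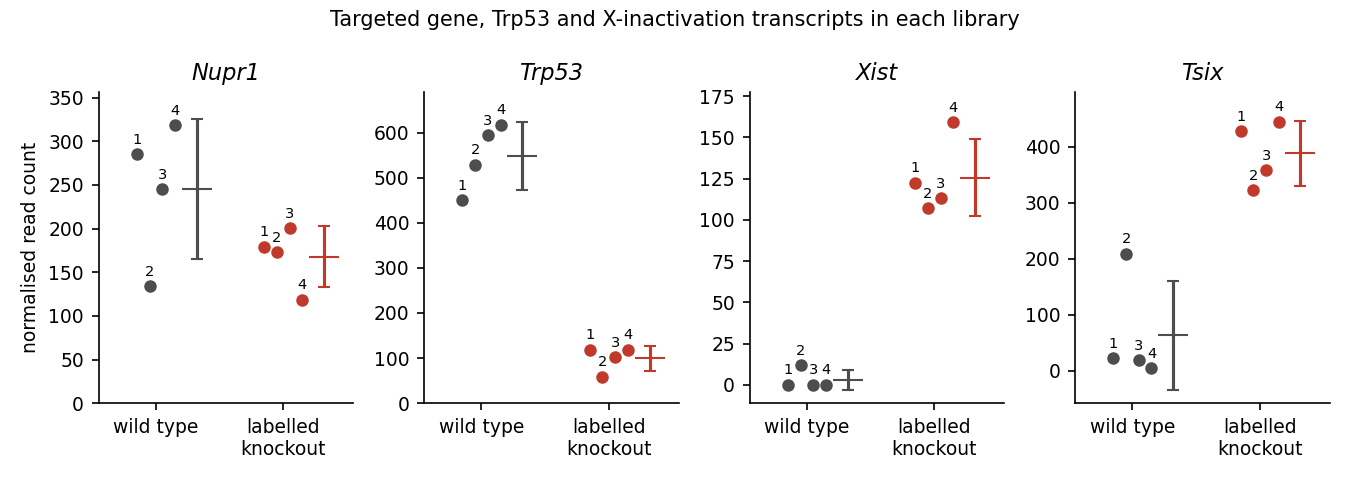
Normalised read counts of Nupr1, Trp53, Xist and Tsix in each wild type library and each library labelled knockout (points, with group mean ± SD, n = 4). Trp53 lay between 58.6 and 118.5 in the libraries labelled knockout and between 450.5 and 617.5 in wild type, whereas the Nupr1 values of the groups overlapped.

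Across the transcriptome 418 of 10989 genes differed, 185 higher and 233 lower in the libraries labelled knockout (limma, adjusted p under 0.05), and 2160 had an unadjusted p under 0.05. The 4 values of each group did not overlap in 390 of the 418, and among all tested genes this held for 11.7% against 2.86% by chance. The count was 881 without wild type library 2 and 237, 155, 151, 114, 110, 61 and 49 without library 4 labelled knockout, wild type library 4, library 3 labelled knockout, wild type library 3, wild type library 1, library 1 labelled knockout and library 2 labelled knockout. Of 57 called genes picked by rule, most of them named here, 34, 56, 34 and 36 passed without wild type libraries 1 to 4 in turn and 27, 23, 35 and 40 without libraries 1 to 4 labelled knockout. In all, 22 passed in each of the 8 fits and 25 in 4 or fewer. Wild type library 2 stood apart from the other 7 along the first principal component (25.6% of the variance), and the second component (22.4%) parted the other 3 wild type libraries (45.7 to 67.3) from those labelled knockout (-61.3 to -24.1), with wild type library 2 (-21.8) beside the latter.

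**Figure D2:**
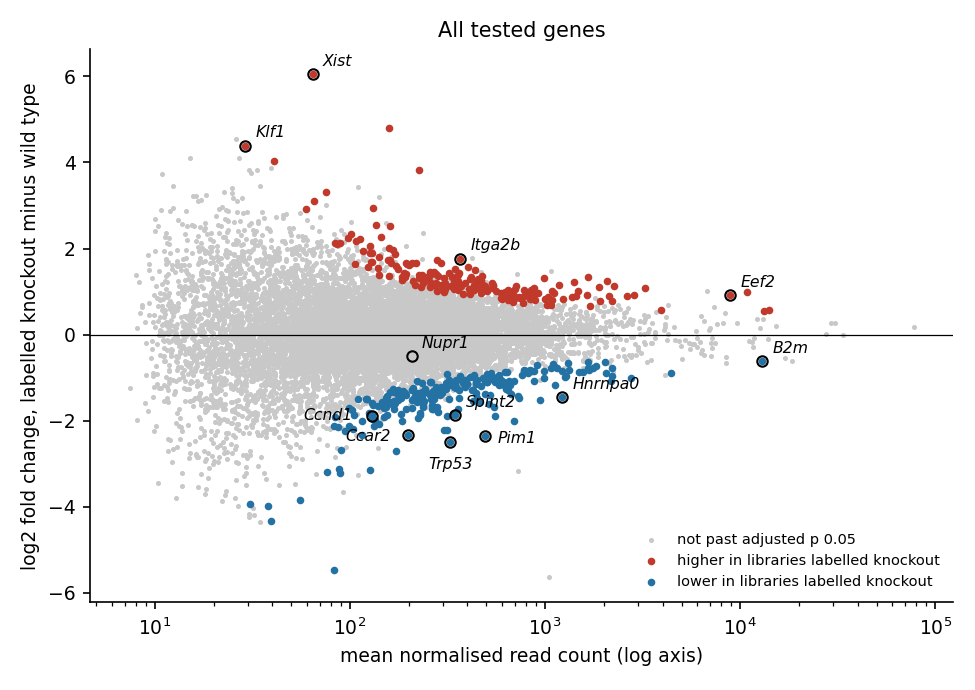
Log2 fold change (libraries labelled knockout minus wild type) of each tested gene against its mean normalised read count (log axis), with the 418 genes past the limma threshold coloured by direction. Of these, 185 lie above 0 and 233 below, and Trp53 is at -2.49.

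The GC content of the transcripts moved with the groups. The Spearman correlation, across genes that are not independent replicates, between GC content and a library's deviation from the gene mean was -0.298, -0.141, -0.313 and -0.191 in wild type libraries 1 to 4 and 0.307, 0.296, 0.247 and 0.155 in those labelled knockout (exact permutation p = 0.0286, the smallest possible, adjusted 0.114). The median GC content was 56.2% in the genes called higher, 42.2% in those called lower and 49.95% in the rest. With the trend in GC content and length removed from each library, a step chosen after seeing the data, 23 genes passed (4 higher, 19 lower). Of the 418 genes, 21 stayed past the threshold, and 1318 genes had an unadjusted p under 0.05. Without wild type library 2 as well, 211 genes passed, 107 of them among the 418. Of the 57 called genes picked by rule, 9 stayed past the threshold after the removal, among them Trp53, Hnrnpa0, Rnf130, Spint2, Pim1, Ccar2, Xist and Dusp5, and the other 48 did not. Some of the 48 kept their log2 change, namely Ccnd1 (-1.90 before and -2.01 after), Gsr (-1.909 and -1.996), Cdk6 (1.72 and 1.88), Pf4 (1.95 and 2.21), Zfp36l1 (-1.49 and -1.50) and Plk2 (-1.73 and -1.68), and others lost most of it, such as Lamp2 (-0.94 and -0.18) and Xiap (-1.15 and -0.22).

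**Figure D3:**
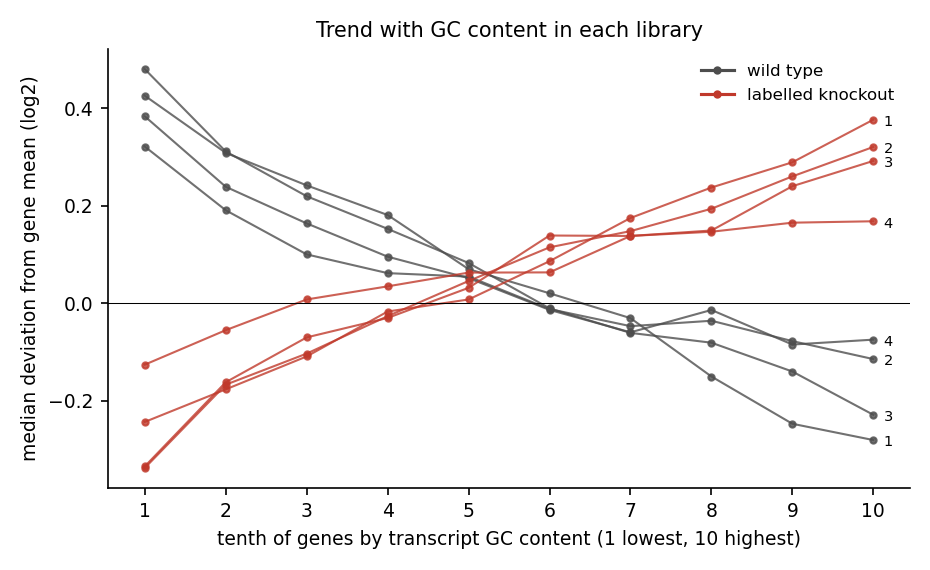
Median deviation from the gene mean (log2) in 10 equal groups of genes ordered by transcript GC content, with 1 line per library. The lines of the 4 libraries labelled knockout climb with GC content and those of the 4 wild type libraries decline.

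Of the genes lower in libraries labelled knockout, Hnrnpa0, an RNA-binding protein, had the smallest p after Trp53. It fell 2.75-fold (log2 -1.46 ± 0.20, SE). Pim1, a survival kinase induced by cytokine signalling, went from 839 ± 526 to 144 ± 36.4 normalised reads. Ccar2, an inhibitor of the deacetylase SIRT1, went from 333 ± 134 to 62.9 ± 12.7, and Spint2, an inhibitor of serine proteases, from 547 ± 148 to 145 ± 27.0 (all SD, n = 4). Rnf130, Tm9sf3, Tmed5, Capza2, Sh3bgrl and Far1 had log2 changes from -1.52 (Tm9sf3) to -1.88 (Sh3bgrl). The limma adjusted p of these 10 genes ran from 0.00283 to 0.00596, and all 11 with Trp53 passed in each of the 8 fits that left out 1 library. After the GC removal 5 of them did not pass, with log2 changes of -0.90 (Tm9sf3), -0.65 (Tmed5), -0.93 (Capza2), -0.96 (Sh3bgrl) and -0.88 (Far1). Exons of Pim1, Ccar2, Tmed5, Sh3bgrl and Far1 overlap those of another gene by 43 to 488 bases, and reads there cannot be assigned.

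Of the genes higher in libraries labelled knockout, 12 are named for their small p. Eef2, the elongation factor that moves the ribosome, went from 6172 ± 777 to 11624 ± 1318 normalised reads, and Nfe2, a transcription factor of platelet formation, from 1486 ± 153 to 2764 ± 74.4 (SD, n = 4). Apoe, a lipid carrier, rose 2.36-fold and Dusp1, a phosphatase that switches off MAP kinases, 2.11-fold. H2-Q7 (1.91-fold) and H2-Q6 (2.31-fold) encode non-classical class I molecules so alike in sequence that reads can be shared between them. Ehmt2, a histone H3 lysine methyltransferase, rose 2.58-fold, Pck2, the mitochondrial PEP carboxykinase, 2.26-fold and Pisd, a mitochondrial lipid enzyme, 1.90-fold. Itga2b, Aldoa and Xist complete the 12, whose limma adjusted p ran from 0.00514 to 0.0109. Ehmt2, Aldoa and Pck2 each passed in 7 of the 8 fits that left out 1 library (highest adjusted p 0.0506, 0.0506 and 0.0544, each without library 2 labelled knockout), and the other 9 in all 8. Only Xist of the 12 passed with the GC trend removed. The log2 change went from 0.92 to 0.46 for Eef2, 0.93 to 0.49 for H2-Q7, 1.21 to 0.83 for H2-Q6, 0.90 to 0.72 for Nfe2, 1.08 to 0.71 for Dusp1, 0.93 to 0.53 for Pisd, 1.24 to 0.74 for Apoe, 1.37 to 0.83 for Ehmt2 and 1.1745 to 1.0605 for Pck2. Exons of Dusp1, Pisd and Pck2 overlap those of another gene by 11 to 1352 bases, as do, among called genes named further on, exons of Ppp1r15a, Gpi1, Ltbp3, Dusp5, Gapdh, Ccnd1, Nop56, Eng, Tpi1, Lbr, Cdk6, Rangap1, Zfp36l1 and Mybbp1a by 12 to 1672 bases.

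Beside the fall of Trp53, the genes that p53 controls did not pass as a set. Of 46 tested p53 target genes, 1 rose, 1 fell and 44 did not pass (3 adjusted over the list alone), where 418 of all 10989 genes passed. An unadjusted limma p under 0.05 was found for 8 of the 46 and for 2160 of all genes. DESeq2 called 3 of the targets, limma-voom 4 and edgeR with TMM factors 2. Ptp4a3, a phosphatase, rose from 516 ± 143 to 1036 ± 172 normalised reads (log2 1.03, adjusted p = 0.0190), and Plk2, a polo-like kinase, fell from 258 ± 124 to 79.1 ± 44.4 (log2 -1.73, adjusted p = 0.0379). Cdkn1a, the cell cycle inhibitor p21, was 113 ± 78.9 against 163 ± 122 (adjusted p = 0.740). Mdm2, the ligase that degrades p53, was 310 ± 65.5 against 308 ± 43.7 (adjusted p = 0.991), Ccng1 was 199 ± 45.4 against 319 ± 35.9 (adjusted p = 0.172), and the death genes Bbc3 and Bax had adjusted p of 0.634 and 0.731. As a set the targets did not differ from other genes (median log2 change 0.07, camera adjusted p = 0.868). Of 21 regulators and partners of p53, Trp53 fell and 20 did not pass (3 adjusted over the list alone). The list had adjusted p = 0.702, with a median of 0.02 while its mean (-0.11) and test pointed down. Rchy1, a ubiquitin ligase for p53, had a log2 difference of -0.90 (adjusted p = 0.0577) and Mdm4 0.23 (adjusted p = 0.573). Ptp4a3 passed in 3 and Plk2 in 2 of the 8 fits that left out 1 library, with the highest adjusted p without library 3 (0.0694) and library 4 (0.0960) labelled knockout, and after the GC removal the log2 change of Ptp4a3 was 0.73 (adjusted p = 0.204).

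Genes of DNA replication were shifted upward as a set in libraries labelled knockout. Of 44 tested G1/S and S phase genes 32 lay above 0, with a median log2 difference of 0.37 (limma camera adjusted p = 0.0432; adjusted p = 0.898 with the estimated correlation of 0.238). Singly, 0 of the 44 passed in limma, 7 had an unadjusted p under 0.05, and 3 passed adjusted over the list alone, while DESeq2 and limma-voom each called 3 and edgeR 0. Rfc2, a subunit of the clamp loader, was 1028 ± 193 against 600.3 ± 141 (adjusted p = 0.0522). The set shift missed the threshold without wild type library 1 (adjusted p = 0.555), without library 4 labelled knockout (0.353), by fry (0.624), with edgeR (0.0571 to 0.0585), with no filter on low values (0.0533) and without a variance trend (0.0725). With the GC trend removed its adjusted p was 4.98e-04 (median 0.35), and adjusted p = 0.751 with an estimated correlation.

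Genes of mitosis and of cell cycle control moved both ways. Of 50 tested G2/M genes, 2 rose, 1 fell and 47 did not pass (3 adjusted over the list alone; median log2 0.22, camera adjusted p = 0.577). Hjurp, the chaperone that loads the centromeric histone, rose 1.77-fold to 1266 ± 144 and Rangap1, the Ran GTPase activator, 2.09-fold to 418 ± 108, while Lbr, the lamin B receptor, fell 1.83-fold to 438 ± 74.4 (limma adjusted p = 0.0425, 0.0425 and 0.0360). The G2/M set passed without wild type library 2 (adjusted p = 0.0339) or without library 2 labelled knockout (0.0474), with adjusted p = 0.876 and 0.890 in these fits with an estimated correlation, and pointed down without wild type library 1 (0.649) or library 4 labelled knockout (0.646). Of 22 cyclin-dependent kinases, cyclins and inhibitors, 2 rose, 1 fell and 19 did not pass (3 adjusted over the list alone; median 0.04, adjusted p = 0.842). E2f1, a driver of S phase entry, rose from 76.7 ± 46.3 to 237 ± 55.3, and Cdk6, the G1 kinase, from 150 ± 128 to 412 ± 126, with wild type library 2 inside the range of the libraries labelled knockout. Ccnd1, cyclin D1, fell from 202 ± 24.7 to 57.8 ± 25.9 (adjusted p = 0.0305, 0.0397 and 0.0234). Each of these 6 genes failed in 5 to 7 of the 8 fits that left out 1 library, with the highest adjusted p without library 1 labelled knockout for Rangap1 (0.167), Lbr (0.128) and Cdk6 (0.119), without library 3 labelled knockout for E2f1 (0.0929), and without wild type library 4 for Hjurp (0.125) and 1 for Ccnd1 (0.0706). Cdk6 (0.0800 to 0.0991) and Hjurp (0.0561 to 0.0772) also missed the threshold in edgeR. After the GC removal the log2 change was 0.76 for Hjurp (0.82 before), 0.68 for Rangap1 (1.0623), -0.56 for Lbr (-0.87) and 1.24 for E2f1 (1.74), with none past the threshold. Mki67, a marker of cycling cells, was 452 ± 238 against 212 ± 167 (adjusted p = 0.264), and Cdkn1c, the inhibitor p57 of quiescent HSCs, 129 ± 55.9 against 174 ± 31.0 (adjusted p = 0.482).

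Markers of megakaryocytes and platelets passed as a set, upward in libraries labelled knockout, with the preset correlation but not with an estimated one. Of 12 tested, 4 rose (Itga2b, Gp9, Vwf and Pf4), 0 fell and 9 lay above 0, with a median log2 difference of 1.37 (limma camera adjusted p = 0.0238; 7 genes adjusted over the list alone, 6 higher and 1 lower). The set had camera adjusted p = 0.188 with an estimated correlation of -0.0118. That lies below the preset 0.01, so a higher correlation does not account for the missed threshold, and its cause was not tested. By fry the set passed (adjusted p = 0.0114). With the preset correlation it passed in each of the 8 fits that left out 1 library (0.00979 to 0.0428), and with an estimated one in none (0.213 to 0.339). Itga2b, the integrin CD41, went from 175 ± 84.5 to 556 ± 109 normalised reads, Vwf, von Willebrand factor, from 614 ± 140 to 1076 ± 159, and Pf4, platelet factor 4, from 55.2 ± 35.7 to 179 ± 41.5 (SD, n = 4; adjusted p = 0.00852, 0.0360 and 0.0493). Gp9, a subunit of the platelet receptor for von Willebrand factor, chosen here after its values were seen, went from 39.3 ± 19.2 to 234 ± 101 (adjusted p = 0.0145). Mmrn1, multimerin, was 740 ± 60.3 against 1042 ± 267 (adjusted p = 0.222). The set also passed with the GC trend removed (adjusted p = 0.00177; adjusted p = 0.193 with an estimated correlation), while none of the 4 genes did so singly, with log2 changes going from 1.76 to 1.28 (Itga2b), 0.82 to 0.36 (Vwf), 1.95 to 2.21 (Pf4) and 2.55 to 2.22 (Gp9). Pf4 missed the threshold in edgeR (0.0786 to 0.0873), with no filter (0.0566), with a filter on CPM (0.0532) and with values rescaled to equal column sums (0.0505). Pf4 passed in 1 and Vwf in 3 of the 8 fits that left out 1 library, with a highest adjusted p of 0.136 for both, without library 1 labelled knockout. Gp9 missed the threshold without library 1 (0.0610) or library 3 (0.0503) labelled knockout.

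Genes of stem cell identity and lineage priming changed in both directions and did not pass as sets. Of 48 tested HSC identity genes, 4 rose, 1 fell and 43 did not pass (9 adjusted over the list alone, 5 higher and 4 lower). In limma 20 of the 48 had an unadjusted p under 0.05, against 2160 of all 10989 tested genes. The list had a median log2 difference of -0.19 (camera adjusted p = 0.566). Beside Itga2b and Vwf, which stand in both lists, Gfi1b, a transcriptional repressor active in stem cells and the megakaryocyte lineage, rose from 325 ± 84.5 to 742 ± 176 and Ltbp3, which binds latent TGF-beta, 2.23-fold (both limma adjusted p = 0.0182). Mllt3, a chromatin reader of HSC maintenance chosen here after its values were seen, fell from 1399 ± 239 to 838 ± 159 (adjusted p = 0.0440). Gfi1b and Ltbp3 missed the threshold without library 1 (0.0681 and 0.0602) or library 2 (0.0560 and 0.0640) labelled knockout. The GC removal took the log2 change of Gfi1b from 1.20 to 0.72 (adjusted p = 0.250), of Ltbp3 from 1.16 to 0.61 (0.321) and of Mllt3 from -0.74 to -0.21 (0.752). Mllt3 passed in 1 of the 8 fits that left out 1 library and missed the threshold with no filter (0.0509). In edgeR it missed with RLE (0.0524), upper quartile (0.0519) and TMM factors (0.0512) and passed with library size alone (0.0478). Of 17 tested multipotent progenitor and lineage priming genes, 2 rose, 0 fell and 15 did not pass (8 adjusted over the list alone, 5 higher and 3 lower; 12 at an unadjusted p under 0.05). Klf1, the master regulator of erythroid genes, went from 1.84 ± 1.43 to 56.3 ± 26.7 (adjusted p = 0.0341), and Pf4 is the other. Klf1 passed in 1 of the 8 fits that left out 1 library (highest adjusted p 0.117, without library 3 labelled knockout) and missed the threshold in limma-voom (0.0638) and after the GC removal (0.154, log2 4.39 before and 3.84 after). The priming list had adjusted p = 0.868, with a median of -0.10 and its test down but a mean of 0.09.

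**Figure D4:**
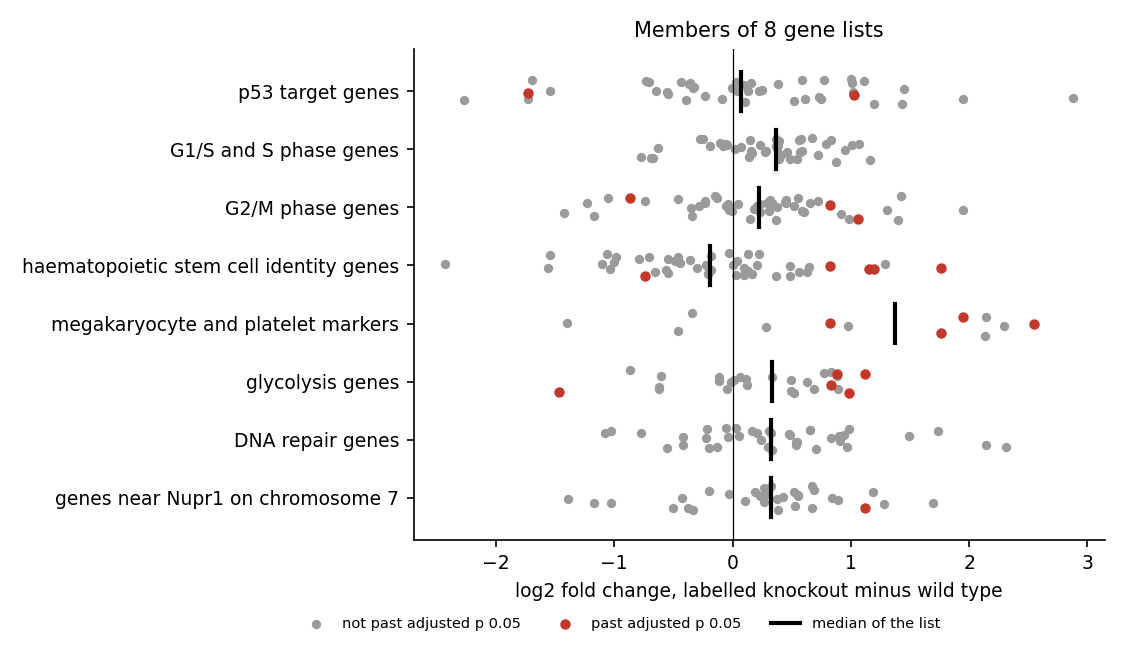
Log2 fold change (libraries labelled knockout minus wild type) of each tested member of 8 gene lists fixed before the data were examined, with members past the limma threshold marked and the list median drawn. The megakaryocyte and platelet markers have a median of 1.37, and the p53 target genes 0.07.

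Enzymes of glycolysis passed as a set, upward in libraries labelled knockout, with the preset correlation but not with an estimated one. Of 27 tested, 4 rose, 1 fell and 22 did not pass (8 adjusted over the list alone, 7 higher and 1 lower), and 18 lay above 0 and 9 below, with a median log2 difference of 0.34 (limma camera adjusted p = 0.0432; adjusted p = 0.600 with an estimated correlation). Gapdh went from 7473 ± 2398 to 14144 ± 1950 normalised reads, Aldoa, aldolase A, from 1442 ± 437 to 3045 ± 357, Gpi1, glucose phosphate isomerase, from 1876 ± 418 to 3408 ± 356 and Tpi1, triose phosphate isomerase, from 894 ± 191 to 1572 ± 239 (SD, n = 4; adjusted p = 0.0230, 0.00852, 0.0174 and 0.0319). Hk2, hexokinase 2, chosen here after its values were seen, fell from 273 ± 102 to 92.2 ± 6.44 (adjusted p = 0.0341; passed in 1 of the 8 fits that left out 1 library). With the GC trend removed the set had adjusted p = 0.471 and none of the 4 higher genes passed (log2 0.98 before and 0.57 after for Gapdh, 1.12 and 0.69 for Aldoa, 0.89 and 0.59 for Gpi1, 0.83 and 0.55 for Tpi1). Hk2 did not pass after the removal either (limma adjusted p = 0.0647), with log2 changes of -1.47 before and -1.63 after. Gapdh and Gpi1 each passed in 5, Aldoa in 7 and Tpi1 in 1 of the 8 fits that left out 1 library. The set also missed the threshold without wild type library 1 (0.138), library 1 (0.0529) or library 2 (0.0514) labelled knockout, by fry (0.149), in edgeR (0.0528 to 0.0543), with no filter (0.0533) and without a variance trend (0.195).

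Genes of respiration and protein synthesis did not pass as sets in the main comparison, though without wild type library 2 the ribosomal protein (adjusted p = 0.0166) and the ribosome biogenesis and MYC target lists (0.0396) did (adjusted p = 0.339 for both with an estimated correlation). Of 76 nuclear genes of oxidative phosphorylation, 2 rose, 1 fell and 73 did not pass (3 adjusted over the list alone; median log2 -0.16, camera adjusted p = 0.319). Uqcrc1 (2.01-fold, adjusted p = 0.0145) and Cyc1 (416 ± 85.6 to 829 ± 153, adjusted p = 0.0236), subunits of respiratory complex III, rose, and Ndufa4, a subunit of cytochrome c oxidase, fell 2.25-fold (adjusted p = 0.0234). Uqcrc1 passed in 6 and Cyc1 and Ndufa4 each in 4 of the 8 fits that left out 1 library, and the GC removal took their log2 changes from 1.0044 to 0.54, 0.9997 to 0.61 and -1.17 to -0.54 (adjusted p = 0.285, 0.256 and 0.370). Of 44 ribosome biogenesis and MYC target genes, 2 rose, 0 fell and 42 did not pass (5 adjusted over the list alone; median 0.31, adjusted p = 0.189). They were Nop56, a core protein of box C/D snoRNA particles (460 ± 140 to 902 ± 110, adjusted p = 0.0257), and Mybbp1a, a nucleolar protein that binds p53 (199 ± 23.5 to 406 ± 101, adjusted p = 0.0494). Both passed in 2 of those 8 fits and had log2 changes of 1.01 and 0.9958 before the GC removal and 0.90 and 0.72 after it (adjusted p = 0.143 and 0.301), and Mybbp1a missed the threshold with no filter (0.0560), a filter on CPM (0.0532), equal column sums (0.0537) and edgeR without factors (0.0537). Of 79 cytosolic ribosomal protein genes, 6 were among the genes analysed, and 0 of the 6 passed in limma, DESeq2 or edgeR (2 at an unadjusted p under 0.05, 0 adjusted over the list alone; median -0.40, list adjusted p = 0.319). Rplp0 and Rplp1 differed by 0.28 and -0.55 on the log2 scale. With the GC trend removed the 6 had a median of -0.61 and adjusted p = 0.00138 (adjusted p = 0.494 with an estimated correlation).

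Stress and redox genes moved both ways. Of 37 immediate early and stress response genes, 1 rose, 2 fell and 34 did not pass (4 adjusted over the list alone). Dusp1 rose, whereas Dusp5, the nuclear phosphatase of ERK, fell from 489 ± 225 to 136 ± 78.7 and Zfp36l1, which degrades AU-rich mRNAs, from 181 ± 54.8 to 61.7 ± 8.65 (limma adjusted p = 0.0206 and 0.0470; Zfp36l1 0.0525 with no filter and 0.0507 with a filter on CPM). The list had adjusted p = 0.702, with a median of 0.06 and its test up but a mean of -0.08. Of 39 endoplasmic reticulum stress and ATF4 genes, Ppp1r15a, the phosphatase subunit GADD34, rose 2.16-fold (adjusted p = 0.0116) and 38 did not pass (2 adjusted over the list alone). Phgdh, of serine synthesis, had a log2 difference of 0.70 (adjusted p = 0.0565), and the list had adjusted p = 0.842 with a median of 0.07 and a mean of -0.02. Of 31 iron, ferroptosis and antioxidant genes, 1 rose, 2 fell and 28 did not pass (6 adjusted over the list alone; median -0.07, adjusted p = 0.702). Gpx4, the enzyme that guards against ferroptosis, rose 1.59-fold (adjusted p = 0.0349), and Prdx1, a peroxiredoxin, fell 1.70-fold and Gsr, glutathione reductase, 3.76-fold (adjusted p = 0.0190 and 0.0235). Of the 8 fits that left out 1 library, Ppp1r15a passed in 6, Dusp5 in 4, Prdx1 in 3, Gsr in 2 and Zfp36l1 and Gpx4 each in 1, and Dusp1 in 8. The GC removal took the log2 change of Gpx4 from 0.66 to 0.24 (adjusted p = 0.632), of Prdx1 from -0.77 to -0.34 (0.430) and of Ppp1r15a from 1.11 to 0.70 (0.181), with Gsr and Zfp36l1 as given above.

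The genes around Nupr1 on chromosome 7 passed as a set, upward in libraries labelled knockout, with the preset correlation but not with an estimated one. Of 33 tested, 24 lay above 0, with a median log2 difference of 0.33 (limma camera adjusted p = 0.0432; adjusted p = 0.188 with an estimated correlation), and 1, Aldoa, passed singly (2 adjusted over the list alone). The annotation entry matched to Aldoa, ENSMUSG00000114515.2, lies from 126800790 to 126809108, and the values of Aldoa are given with the glycolysis genes. For a symbol with more than 1 protein-coding entry the last was used for positions and exon overlaps, so another entry of the symbol may lie elsewhere. The list has a median GC content of 55.8%. With the GC trend removed its median was -0.09 and its adjusted p 0.928. It also missed the threshold without wild type library 1 (0.0894), in edgeR (0.0528 to 0.0543) and without a variance trend (0.0725). By fry, with the GC trend left in, it passed (adjusted p = 0.00159).

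Markers of other bone marrow cells, fixed as lists because a sort can carry such cells, did not pass as sets apart from the megakaryocyte list, where a list had enough genes to be tested. Lyz2, of monocytes and macrophages, was 2077 ± 509 in libraries labelled knockout and 2134 ± 705 in wild type, and 0 of the 7 genes of its list passed in limma, DESeq2 or edgeR (0 at an unadjusted p under 0.05; adjusted p = 0.702). The 3 tested B cell markers all lay below 0 (median log2 -1.07). Ighm, the heavy chain of B cells, was 6740.4 and 1386.9 in wild type libraries 4 and 3 and at most 166.1 in the other 6 (adjusted p = 0.242). Cd79b, its signalling partner, was 551 ± 289 in wild type and 234 ± 29.98 in libraries labelled knockout (adjusted p = 0.0868). H2-Ab1, a class II chain of dendritic cells, was also highest in wild type libraries 4 and 3 (1606.9 and 1023.0), and Tcf4 had a log2 difference of -1.09 (adjusted p = 0.121). Of 8 dendritic cell markers 0 passed in limma or edgeR and 1 in DESeq2 (2 at an unadjusted p under 0.05; list median -0.76, adjusted p = 0.577, 0.0396 without wild type library 2, and 0.0156 with the GC trend removed as well; adjusted p = 0.339 and 0.372 in these fits with an estimated correlation). Of 9 endothelial markers 2 rose, Eng (1.90-fold, adjusted p = 0.0305) and Tie1 (176 ± 45.3 to 465 ± 47.8, adjusted p = 0.0125; chosen after its values were seen), with Eng past the threshold in 1 and Tie1 in 7 of the 8 fits that left out 1 library and log2 changes going from 0.92 to 0.47 and 1.43 to 0.98 with the GC trend removed (adjusted p = 0.435 and 0.154), while Egfl7 was 328 ± 75.2 against 371 ± 103. That list had adjusted p = 0.577, with a median of -0.16 but a mean of 0.08 and its test up.

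Lists with fewer than 5 tested genes were not tested as sets, and 0 of their genes passed in limma except on the X chromosome. Of 4 erythroid markers, Car2 was 5147 ± 876 against 3354 ± 1212 and Tfrc 121 ± 38.5 against 222 ± 108. Padi4, of neutrophils, was 78.9 ± 25.6 against 33.7 ± 12.1, and Gata2, listed for mast cells and also a stem cell factor, 1896 ± 268 against 1489.9 ± 387. Among 3 T and NK cell markers Nkg7 was 92.8 ± 29.7 against 126 ± 111 and Klrb1c 42.5 ± 33.8 against 60.7 ± 47.4. Among 3 bone and stromal markers Runx2 was 203 ± 30.6 against 392.2 ± 64.7 (limma adjusted p = 0.0523) and Pdgfrb 30.9 ± 29.5 against 45.1 ± 34.6. Unadjusted p was under 0.05 for 1 erythroid, 1 neutrophil, 2 B cell and 1 stromal gene, and DESeq2 called 1 B cell and 1 stromal gene and edgeR 0 of these. Of the 3 tested Y-linked and X-inactivation genes, Xist and Tsix rose. None of the 26 mitochondrially encoded genes was among those analysed.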

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

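The counts over other splits, the counts of calls that outlast the GC removal or end for one reason or another, the gap in GC correlation and both tests on Nupr1 were chosen only after the results were seen. For the other tests of causes here, bounds were written before the tested values, apart from an added demand named below. They were written after the patterns they address had been seen, and the GC removal they use was itself chosen after seeing the data.

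The 418 genes that differed were rich in GC when higher and poor in GC when lower in libraries labelled knockout. Of the 35 splits of the 8 libraries into 4 and 4, 1, the real one, gave as many genes (418, highest other 1). With 35 splits no rarer outcome was possible, and the test was chosen after the count was seen, so chance is not excluded. A trend with GC content and length was not the whole cause for 21 genes, Trp53 among them, which passed before and after its removal. For the 394 calls that ended, a median of 65.1% of the log2 change remained (1.16 to 0.78 for 181 higher genes, SD 0.650 and 0.693, and -1.33 to -0.83 for 213 lower genes, SD 0.647 and 0.769) with nearly the same standard error (0.276 and 0.279, 0.303 and 0.305), and the calls ended for more than one reason. At most 50% of the change remained in 89 of them and more than 75% in 116, of which 25 had a change as large or larger, and 71 kept a p within the largest called before and ended by the adjustment over all genes. Simulated data with the trend of the real libraries and no changed gene gave 4 calls, but a simulation decides nothing for single genes, and for these the trend and a change of the genes themselves cannot be told apart. The trend may come from library preparation or from the genotype, which the design confounds, since a gap of 0.295 parts the lowest correlation in libraries labelled knockout from the highest in wild type, and the widest range within a group was 0.172.

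Xist reads set all 4 libraries labelled knockout apart from wild type libraries 1, 3 and 4, and in wild type library 2 Xist stood at 11.82 with the others at 0. A difference in sex between the groups could contribute to the calls and stays open: X- and Y-linked genes made up 4.07% of the called and 3.197% of the other tested genes (Fisher's exact p = 0.322), but the single wild type library with Xist lay nearer the wild type mean for only 46.0% of the 881 genes called from the other 7 libraries. Uty was low in wild type library 2 (3.0), as in libraries labelled knockout, which goes with its Xist and Tsix reads. Kdm5d, Y-linked as well, goes the other way, with 33.5 in wild type library 2 and 19.9 to 68.2 in the other wild type libraries. It was also read in every library labelled knockout (11.5 to 25.9). Of 4 X-linked genes that escape inactivation, the means of Kdm6a and Kdm5c were higher in libraries labelled knockout (82.9 against 56.4 and 107.7 against 82.2) and those of Eif2s3x and Ddx3x lower (782 against 994 and 1258 against 1487), with none past the test. Those 46.0% met the bound set for sex and for a mislabelled library, and for the latter the demand that it lie as near the mean of the libraries labelled knockout as those do when held out was added after that value was seen. Wild type library 2 lay 54.6% of the way from the wild type mean over the 881 genes. Held-out libraries labelled knockout lay 1.04 to 30.5% of the way from their own mean, but over other sets of 49 to 237 genes. Held-out wild type libraries 1, 3 and 4 lay 7.63, 18.4 and 18.1% of the way from theirs, over other sets of 110, 114 and 155 genes. They were nearer the wild type mean for 88.2, 84.2 and 86.5% of these genes. Trp53 in wild type library 2 (528.2) was in the wild type range. This library also lay at -126.5 on the first principal component, apart from the other 7 (0.812 to 36.9), with the fewest genes with reads (11018). A mislabelled, a mixed, an outlying and a true wild type library therefore cannot be told apart. After the GC removal wild type library 2 lay 71.6% of the way over 206 genes and nearer the wild type mean for 35.4% of them. For these 206 genes its weaker GC trend therefore does not account for its place. They were called anew after the removal, so these values do not decide the question for the 881 genes.

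Nupr1 reads were present in every library labelled knockout, at 68.3% of the wild type mean. If the allele left no Nupr1 reads, a single wild type library under a knockout label would leave the other 3 with almost none, and all 4 had more than 30, the fewest being 123. If the allele does leave reads, these counts say nothing of a single wrong label. A targeted allele that still gives a transcript counted under the gene is a candidate explanation that 68.3% neither requires nor excludes, because a value per gene cannot show the deleted exons. A wrong genotype of the whole group is open as well, with no value here that decides it, and no biological explanation was tested.

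Among 194 groups of 4 libraries examined, 8 had a library whose gap to the nearest other exceeded Dixon's critical share of the group's range, a share that chance alone gives in about 1 in 20, and Xist in wild type library 2 is 1 of them. Genes with reads numbered 11018 in wild type library 2 and 11485 to 11553 in the other wild type libraries. Gpi1 was 1251 in wild type library 1 (2051 to 2133 in the others) and 3941 in library 3 labelled knockout (3215 to 3252 in the others). In library 3 labelled knockout Ighm was 166.1 (0 to 17.5 in the others) and H2-Ab1 601.7 (179.6 to 215.7 in the others). Fn1, listed for macrophages, was 297.1 in wild type library 3 and 11.8 to 24.4 in the others. Pdgfrb was 75 in library 4 labelled knockout and 14.1 to 19.95 in the others.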

How the results depend on the processing

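The removal of the GC and length trend, added values of 5 and 10, and rescaling by TMM factors or column sums were chosen only after the results were seen. EdgeR with TMM factors, the main test first planned, was kept as an alternative on recovered reads. Camera without a variance trend, its default, had been run before the main list test, which was given the trend after that. In fits with a library left out or the GC trend removed, camera with an estimated correlation was chosen after the results were seen. The other alternatives were planned, among them camera with an estimated correlation in the main comparison.

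Trp53 kept its direction and passed the threshold in every alternative run, with log2 changes from -2.26 to -2.82, and Nupr1 passed in none, with differences from -0.34 to -0.89. No gene called in the main comparison was called in the opposite direction under any alternative. The count of genes stayed within 1.5 times of 418 with edgeR (324 to 341), no filter (351), a filter on CPM (366), added values of 5 (487) and 10 (527), and rescaling by TMM factors (416) or to equal column sums (399). The replicate numbers pair no mice in the labels or the values: same-numbered libraries correlated, across genes that are not independent replicates, from -0.0566 to 0.0148 and differently numbered ones from -0.0464 to 0.0732, and 0 of 8 correlated best with its own number. In simulated data with the dispersions of these libraries 16% of genes changed 2-fold and 63% of those changed 4-fold were called, and what limits this was not tested.

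The number of genes that differed was 782 with DESeq2 (339 higher, 443 lower, 415 of them shared with the 418), 646 with limma-voom and sample weights (286 higher, 360 lower, 398 shared), 277 with the replicate number as a block (115 higher, 162 lower), 745 at adjusted p under 0.1 (343 higher, 402 lower) and 1 when tested against 1.5-fold (0 higher, 1 lower; 614 at an unadjusted p under 0.05). It was 23 with the GC and length trend removed (4 higher, 19 lower) and 211 with wild type library 2 also left out (107 higher, 104 lower). With edgeR and library size alone 120 genes were higher. With 1 library left out it ran from 49 (without library 2 labelled knockout) to 881 (without wild type library 2), the higher genes from 14 to 452 and the lower from 35 to 429. The stricter and looser thresholds changed the counts by construction, and for the other alternatives the cause was not tested.

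Of the 57 called genes picked by rule, 57 passed with DESeq2 and 56 with limma-voom, 52 or 53 with each edgeR setting, 52 with no filter, 53 with a filter on CPM, 45 with the block, 9 with the GC trend removed and 25 with wild type library 2 also left out. B2m, lower in the main comparison, had log2 differences of 0.0888 and 0.14 under the last pair. Among genes not called, the same pair turned the sign of Mmrn1 (0.0137 and 0.0257), Gata2 (-0.11 and -0.12), Lyz2 (0.0538 and 0.00219) and Mdm2 (0.16 and 0.31), and the second that of Ccng1 (0.0104). Mdm2 was also 0.00841 with DESeq2, 0.0688 with limma-voom, and in edgeR 0.00811 with RLE, 0.0176 with upper quartile factors, 0.00704 with library size and 0.00725 with TMM. Nkg7 was -0.43 with DESeq2, and in edgeR -0.43 with RLE, -0.42 with upper quartile factors, -0.43 with library size and -0.43 with TMM. With 1 library left out the log2 difference ran from -0.85 to 0.0453 for Cdkn1a, -1.55 to 0.38 for Klrb1c, -0.77 to 1.51 for Nkg7, -0.39 to 0.0261 for Egfl7, -0.15 to 0.18 for Lyz2 and -0.103 to 0.0967 for Mdm2. The cause was not tested for any of these.

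The number of lists past the threshold, 4 in the main comparison, was 0 with an estimated correlation, 1 without a variance trend, 2 by fry, 1 with edgeR and RLE factors, 1 with library size, 1 with TMM, 2 with no filter, 8 with the GC trend removed and wild type library 2 left out, and 1 to 9 with 1 library left out (1 without wild type library 1, 9 without wild type library 2), and 0 in each of these last 9 fits with an estimated correlation. The adjusted p of the G1/S and S phase list was 0.898 with an estimated correlation, 0.0725 without a variance trend, 0.624 by fry, 0.0585, 0.0571 and 0.0577 with edgeR (RLE, library size, TMM), 0.0533 with no filter and 0.0166 to 0.555 with 1 library left out. That of the G2/M list was 8.43e-05 with the GC trend removed and wild type library 2 left out (adjusted p = 0.673 with an estimated correlation) and 0.0339 to 0.914 with 1 library left out, pointing down without wild type library 1 or library 4 labelled knockout. The p53 target list pointed down with the GC trend removed (0.731), with wild type library 2 also left out (0.831) and without library 1 labelled knockout (leave-one-out range 0.822 to 0.927). The cause was not tested.

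Other lists turned direction at these adjusted p. With the GC trend removed they were cyclin-dependent kinases (0.757), immediate early genes (0.190), endoplasmic reticulum stress (0.840), apoptosis (0.665) and mTOR (0.748). With wild type library 2 also left out they were immediate early genes (0.00120; adjusted p = 0.469 with an estimated correlation), autophagy (0.986), apoptosis (0.883), iron and antioxidant genes (0.986), mTOR (0.986) and endothelial markers (0.986). Without a variance trend and by fry they were lineage priming (0.955 and 0.770) and apoptosis (0.955 and 0.928). The mTOR list did so with no filter (0.947), a filter on CPM (0.987) and the block (0.900). With 1 library left out the adjusted p ran from 0.678 to 0.934 for cyclin-dependent kinases, 0.694 to 0.954 for lineage priming, 0.0994 to 0.934 for immediate early genes, 0.808 to 0.934 for apoptosis and 0.868 to 0.973 for mTOR, each with a turn of direction in at least 1 fit. The share of the 50 most abundant genes, 0.144 percentage points higher in libraries labelled knockout, ran from -0.504 to 0.495 with 1 library left out. The cause was not tested.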

Other observations

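The removal of the GC trend, and the choice of the genes named after it, were made only after the results were seen, as was the variance trend in the list test, and the lists themselves were fixed before.

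Interferon response genes did not pass as a set in the main comparison, but did with the GC trend removed and wild type library 2 left out (adjusted p = 0.0116; adjusted p = 0.469 with an estimated correlation). Of 48 tested interferon response genes, 0 rose, 2 fell and 46 did not pass (8 adjusted over the list alone, 4 higher and 4 lower; median log2 0.21, limma camera adjusted p = 0.577). Trim30a, an interferon-induced regulator of NF-kappaB signalling, fell from 759 ± 216 to 278 ± 25.4 normalised reads, and B2m, the light chain of class I molecules, from 15659 ± 1419 to 10172 ± 770 (SD, n = 4; adjusted p = 0.00812 and 0.0145), while H2-Q7 and H2-Q6, heavy chains of that class, rose. B2m missed the threshold without library 1 (0.06003) or 2 (0.0620) labelled knockout or wild type library 3 (0.0504), and its log2 difference was 0.09 with the GC trend removed, when that of Trim30a went from -1.40 to -0.82 (adjusted p = 0.195). DNA repair genes had a median log2 difference of 0.32 (27 of 39 above 0, camera adjusted p = 0.118), and 0 passed in limma or edgeR and 1 in DESeq2 (7 at an unadjusted p under 0.05, 0 adjusted over the list alone). In that list Rnf8 and Xrcc1, of double and single strand break repair, differed by 0.98 and 0.96 (adjusted p = 0.105 and 0.115), and the list passed without wild type library 2 (0.0496, and 0.0491 with the GC trend removed as well) or library 3 labelled knockout (0.0400). With an estimated correlation these 3 fits gave adjusted p = 0.339, 0.3695 and 0.2215.

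Genes of cell death, autophagy and nutrient signalling changed in few members. Of 26 apoptosis genes, Xiap, an inhibitor of caspases, fell from 465 ± 135 to 210 ± 63.5 (limma adjusted p = 0.0411) and 25 did not pass (1 adjusted over the list alone; median -0.04, adjusted p = 0.868), with Birc3 at -1.42 (adjusted p = 0.0996). Of 40 autophagy and lysosome genes, Lamp2, a lysosomal membrane protein, fell from 563 ± 105 to 299 ± 87.7 (adjusted p = 0.0493) and 39 did not pass (0 adjusted over the list alone; median 0.16, adjusted p = 0.702), with Atg5 at -0.86 (adjusted p = 0.161). Lamp2 missed the threshold in edgeR (0.0636 to 0.0676) and with no filter (0.0565), a filter on CPM (0.0532), or rescaling by TMM (0.0502) or column sums (0.0503). With the GC trend removed the log2 change of Lamp2 went from -0.94 to -0.18, that of Xiap from -1.15 to -0.22 and that of Pik3cd from 0.84 to 0.41 (adjusted p = 0.840, 0.817 and 0.475). Of 24 mTOR, PI3K and FOXO genes, Pik3cd, the delta catalytic subunit of PI3K, rose from 438 ± 87.7 to 769 ± 19.7 (adjusted p = 0.0370) and 23 did not pass (7 adjusted over the list alone, 4 higher and 3 lower), with Mlst8 at 1.40 (adjusted p = 0.0794). That list had adjusted p = 0.992, with a median of -0.20 and a mean of -0.04 while its test pointed up. Pik3cd and Lamp2 passed in 1 and Xiap in 2 of the 8 fits that left out 1 library, with the highest adjusted p (0.107, 0.144 and 0.133) without wild type library 3.

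Of the 21 genes past the threshold before and after removal of the GC trend, 18 were lower in libraries labelled knockout. The removal lowers the log2 change of GC-rich genes, which by construction favours a high GC content here. These 18 had a median GC content of 54.4% against 42.2% in all genes called lower. Chosen here after their values were seen, they include Pfn1, profilin (log2 -2.22 after the removal), Basp1, a membrane-bound signalling protein (-2.44), Zfp36l2, which degrades AU-rich mRNAs (-0.89 before and -1.23 after), Larp1, a regulator of ribosomal protein mRNAs (-1.56 and -1.84), and Rcc2, of mitotic spindle assembly (-1.07 and -1.54). The 3 higher genes were Xist, Yod1, a deubiquitinase (1.08 and 1.81), and Marf1, a regulator of RNA stability (1.51 and 1.72). Arf6 (-1.29) and Ctla2b (1.09) passed only after the removal.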
